A study of Mus musculus with 18 samples.

How the data were processed

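RNA was sequenced from whole urinary bladders of female BALB/c mice aged 8 weeks, in 18 libraries that form 6 groups of 3 mice. Groups were read from the sample titles. Mice ate a normal or a vitamin A-enriched diet from 1 week before an intraperitoneal injection of cyclophosphamide (150 mg/kg) or saline. Cyclophosphamide is an alkylating drug whose metabolites reach the urine and injure the urothelium, the epithelium that lines the bladder. Bladders were taken 1 or 3 days after cyclophosphamide and 1 day after saline, so the comparisons of 3 days with saline also differ in the day of collection. The labels give the diet as 566081 UI of retinyl acetate per kg, while the series description names retinyl palmitate at 36 times the usual amount, and both are given here because they differ. Mice were housed in groups of 3, and cages are not given per mouse, so cage and group may coincide. Libraries were made from total RNA with an NEBNext Ultra kit.

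Per the submitters' processing notes, GRCm39, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used. Their roles, the strandedness and the treatment of reads with several alignments are not given in the sources used here. The deposited gene table holds whole-number counts per gene for each library. A second deposited table holds FPKM values, which equal the count per kilobase of gene length, scaled by a library total that differs from the sum of counts by a factor of its own in each library. The authors' tables of the 3 diet comparisons hold a log2 ratio of the normal over the vitamin A diet, an unadjusted p-value, an adjusted p-value and a normalised signal, the group mean of counts divided by library factors. From their values, these tables list genes with an unadjusted p under 0.05 only. The authors' log2 ratios are printed here with the sign turned, as vitamin A over normal.

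The table lists 60750 features, of which 14417 are unnamed features that carried 0.474% to 0.8097% of the counts of a library. They were left out of the library sizes and the main tests, which leaves 46333 named genes. Totals ranged from 19554132 to 34598952 counts per library. Mitochondrial genes took 1.675% to 3.822% of the counts and the 10 most abundant genes 4.523% to 6.557%. After edgeR's filter on low counts 19323 genes were tested. Intervals and floors given for genes with few counts cover counting error only.

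Counts were tested in R 4.3.3 with edgeR 4.0.16, by its robust quasi-likelihood test with TMM scaling, 1 mean per group over all 18 libraries and 12 residual degrees of freedom. There were 11 contrasts. They were the diet effect in each of the 3 conditions, cyclophosphamide at 1 day against saline on each diet, 3 days against 1 day on each diet, 3 days against saline on each diet, the interaction of diet with cyclophosphamide at 1 day, and the interaction of diet with time after cyclophosphamide. Adjusted p-values are Benjamini-Hochberg values per contrast, with a threshold of 0.05, and all tests are 2-sided. Expression is given as counts per 1000000 counts of the library (CPM), mean ± SD over 3 mice, and changes as log2 ratios from the fit. A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group. A gene with 1 to 3 counts in a group is given as a ratio with its exact 95% (Clopper-Pearson) counting interval. Exact permutation of 3 against 3 libraries cannot go below a p of 0.1, so single genes rest on the model that shares information across genes.

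Gene lists numbered 27, all written from general knowledge before the data were examined, as were the contrasts, the main test and the naming rule. They cover retinoid handling, retinoic acid receptors and target genes, umbrella cell and urothelial differentiation, basal urothelium, squamous keratinisation, cell cycle, p53 targets and DNA damage, acute inflammatory cytokines and chemokines, interferon response, neutrophil markers, macrophage and monocyte markers, lymphocyte markers, mast cell and eosinophil markers, smooth muscle, fibroblast markers, matrix remodelling and wound genes, urothelial growth factor signalling, tight junction and barrier, oxidative stress and glutathione, endothelium, nerve and Schwann cells, adipocytes, skeletal muscle, mesothelium, red blood cells, immediate early and dissociation stress, and female genital tract and other epithelia. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares a list with all other genes. Its p-values were adjusted over 297 tests of lists and contrasts. Of these, 141 passed with the preset correlation and 21 of them held with a correlation estimated from the residuals. In the 141 tests the median, the mean and the test had the same sign. Members were also counted with p-values adjusted over the list alone.

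Named genes follow a rule. In each contrast they are up to 10 genes each way with the largest log2 change among genes past the threshold, with a mean log2 CPM of at least 1, an ordinary gene symbol and groups that do not overlap. To these were added up to 4 members with the smallest p from each list described, the 5 smallest p where fewer than 5 genes passed, and in diet contrasts every passing member of the retinoid handling list and always Cyp26a1, Cyp26b1, Rarb, Dhrs3, Lrat and Crabp2. Krt5, Krt14, Krt20, Upk1a, Upk1b, Upk2, Upk3a, Mki67, Cdkn1a and Il6 are always named. Some genes that the rule selects are not reported here.

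The procedure was tested on simulated data with 200 changed genes per contrast, drawn from the fitted means and spread. It recovered 32% to 48% of genes changed 2-fold and 61% to 81% of genes changed 4-fold, with 2 to 10 false calls. A list shifted 1.5-fold was called in 9 of 9 contrasts and none of 234 tests of other lists was called (0). Simulated genes were drawn independently of each other. The simulation therefore cannot show how often the list test calls falsely when genes are correlated. Each simulated gene also had the same spread in all 6 groups, while the common dispersion of the real groups ran from 0.02909 to 0.153. Its recovered shares and false calls therefore do not hold for contrasts between groups of unequal spread. Gene tests of each contrast were computed again with RLE scaling, DESeq2 1.42.0, no filter on low counts or a fit of only its groups. They were also repeated with the replicate number as a block and without each library in turn. Diet contrasts were tested with limma on log2 of FPKM + 1 as well. List tests were repeated in camera with an estimated correlation or with the block, and under none of the settings above apart from that block. Added after the data were seen were the unnamed features included, the fit without the 2 libraries least like their group, limma-voom with sample quality weights, DESeq2 on the 6 libraries of a diet contrast, and the retinoid lists without Cyp26b1. The reference annotation at hand was of another genome build, so coordinates come from the deposited table. Reads between near-identical copies (haemoglobin, Gsta, H2, Sprr2, Gsdmc and Krt6a genes) are uncertain in their assignment, and H2 genes of BALB/c differ in sequence from the reference strain.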

Results

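The question was how extra dietary vitamin A changes gene expression in the mouse bladder at rest and while its lining regrows after cyclophosphamide. Vitamin A is turned into retinoic acid, a ligand of nuclear receptors that sets the fate of epithelia. All values are from 3 mice per group, and log2 changes on diet are vitamin A over normal. RNA came from whole bladders, so a change can reflect the share of a cell type or expression within it. These were not told apart, and layers named below are those of the marker genes.

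In saline mice the diet raised Cyp26b1, which encodes an enzyme that breaks down retinoic acid and is itself induced by it. Cyp26b1 (chromosome 6, 84548396 to 84570890, minus strand) rose from 4.68 ± 2.82 to 45.4 ± 13.8 CPM (log2 3.26, SE 0.40, adjusted p = 0.0035). Elf5, an epithelial transcription factor on chromosome 2 (103242443 to 103281334), rose from 16.7 ± 2.80 to 61.5 ± 10.7 CPM (log2 1.88, adjusted p = 0.00602). Retinoic acid receptors and target genes lay higher as a group, with 23 of 26 measured members above 0 and a median log2 of 0.32. Adjusted over the list alone 5 of these targets rose, against 1 over all genes (adjusted p = 1.07e-09 for the list, or 0.00108 with an estimated correlation). Retinoid handling genes, which store, transport and oxidise the vitamin, had a median of 0.19, with 1 member risen over all genes and 2 adjusted over the list alone (adjusted p = 2.36e-05, or 0.0229 with an estimated correlation). Without Cyp26b1 the target list stayed past the threshold (adjusted p = 1.32e-06, or 0.00564 with an estimated correlation), while retinoid handling passed with the preset value alone (0.00413, or 0.123 with an estimated correlation). Lrat, the enzyme that esterifies retinol for storage, had 16.3 ± 4.90 against 5.70 ± 3.14 CPM (log2 1.51, adjusted p = 1). Dhrs3, which reduces retinal, had 349 ± 14.2 against 244.5 ± 13.3 CPM (log2 0.51, adjusted p = 0.933). Rarb was at 0.58 and Crabp2 at 1.15, neither past the threshold. Cyp26a1, a related gene, had 0 to 16 counts per library and was not tested. Of the lining's markers, the basal keratin Krt5 had 605 ± 37.5 against 1011 ± 66.4 CPM (log2 -0.74, adjusted p = 0.746), and the umbrella cell genes Upk2 (-0.20), Upk1a (0.02), Upk3a (0.01) and Krt20 (-0.36) did not pass. Neither did Krt14 (0.7), Upk1b (-0.02), Mki67 (1.01) or Cdkn1a (0.47), and Il6 had 1 count in each group, too few for a fold. Lists outside the lining passed only with the preset correlation. They were interferon response genes (median 0.51, adjusted p = 4.25e-09, or 0.242 with an estimated correlation), macrophage markers (0.38, adjusted p = 0.000173, or 0.337 with an estimated correlation) and adipocyte genes (2.33, adjusted p = 4.2e-11, or 0.239 with an estimated correlation). So did red blood cell genes (adjusted p = 0.0436, or 0.411 with an estimated correlation), cell cycle genes (0.08, adjusted p = 0.0375, or 0.802 with an estimated correlation) and immediate early genes (-0.25, adjusted p = 0.00428, or 0.562 with an estimated correlation). Cyp26b1 and Elf5 were the 2 genes past the threshold, and 730 of 19323 had an unadjusted p under 0.05 where 966 are expected by chance. Next by p were Eln (1.18, adjusted p = 0.119), Gsdmc3 (1.25, 0.119) and Gsdmc2 (1.24, 0.15). Without normal diet replicate 1 there were 0 genes in edgeR (Cyp26b1 log2 3.23, adjusted p = 0.0731; Elf5 0.119), while DESeq2 on all libraries called 17 genes. Elf5 was also lost without normal diet replicate 3 (0.0838) or vitamin A replicate 2 (0.0562), which left 1 gene each.

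**Figure D1:**
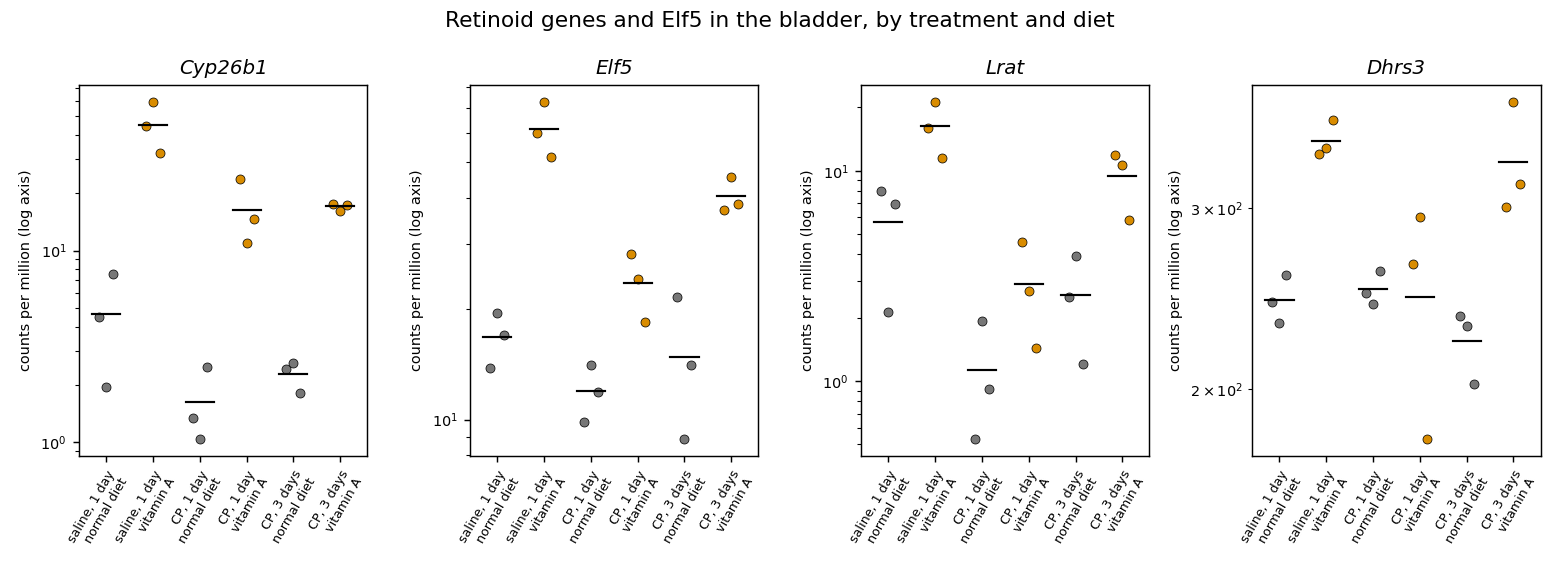
Expression of Cyp26b1, Elf5, Lrat and Dhrs3 in CPM on a log axis, by treatment and diet, where points are the 3 libraries of a group and bars are group means. Cyp26b1 rose with the vitamin A diet in all 3 conditions, by log2 3.26, 3.32 and 2.90.

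At 3 days after cyclophosphamide Cyp26b1 was again the gene that rose with the diet, from 2.27 ± 0.41 to 17.0 ± 0.71 CPM (log2 2.90, SE 0.40, 7.47-fold, adjusted p = 0.0197). It was the 1 gene past the threshold, with 727 at an unadjusted p under 0.05. Higher without passing were Lrat (9.48 ± 3.20 against 2.55 ± 1.37 CPM, log2 1.88, adjusted p = 0.994) and Dhrs3 (333 ± 42.3 against 223 ± 17.9 CPM, log2 0.58, adjusted p = 0.994), with Rarb at 0.42 and Crabp2 at 0.69. Retinoic acid target genes lay higher as a list (median 0.17, 4 risen adjusted over the list alone against 1 over all genes, adjusted p = 2.48e-05, or 0.00862 with an estimated correlation). Without Cyp26b1 that list had an adjusted p of 0.00204 (0.0394 with an estimated correlation). Retinoid handling had a median of 0.17, with 3 members risen adjusted over the list alone against 1 over all genes (adjusted p = 0.00143, or 0.0705 with an estimated correlation), and without Cyp26b1 an adjusted p of 0.0434 (0.242 with an estimated correlation). Elf5 had 40.4 ± 4.61 against 14.8 ± 6.33 CPM (log2 1.45, adjusted p = 0.157; 0.0173 without normal diet replicate 1). Klf4, a differentiation factor of epithelia, had 33.3 ± 7.66 against 62.6 ± 7.75 CPM (log2 -0.91, adjusted p = 0.36), Gm9530 was at 2.08 (0.36), and Gm22442 had 67 counts against 0, at least 27.4-fold higher (0.36). No lining, division or damage marker passed, with Krt5 at -0.37, Krt14 at -0.26, Upk2 at -0.07, Mki67 at -0.62 and Cdkn1a at -0.06 (adjusted p = 0.994 for each). Krt20 (-0.52), Upk1b (-0.1), Upk1a (0.04), Upk3a (0.2) and Il6 (-0.36) did not pass either. Cell cycle genes (median -0.31, adjusted p = 9.9e-06, or 0.552 with an estimated correlation), endothelial genes (-0.28, 0 of 17 above 0, adjusted p = 8.47e-08, or 0.197 with an estimated correlation), smooth muscle genes (0.36, adjusted p = 2.64e-05, or 0.533 with an estimated correlation) and immediate early genes (-0.29, adjusted p = 0.0303, or 0.664 with an estimated correlation) did not hold. Vitamin A replicate 2 stood apart here, with the largest share of counts on genes shorter than 1 kb (13.11%), the lowest correlation with its own group (0.9478) and the lowest sample weight (0.152) of the 18 libraries. It also had the highest mean of smooth muscle genes (log2 CPM 9.038) and the lowest of basal genes (5.958) among the 3 of its group, and the list tests were not repeated without it. The Cyp26b1 call ended when any 1 of the 6 libraries was left out, with an adjusted p of 0.119, 0.183 or 0.362 without normal diet replicate 1, 2 or 3 and of 0.105, 0.153 or 0.0678 without vitamin A replicate 1, 2 or 3, although its log2 change stayed between 2.76 and 3.00.

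At 1 day after cyclophosphamide the diet changed single genes in both directions. Among those that rose with vitamin A were Hbegf, a ligand of the epidermal growth factor receptor, the integrin Itga3, and Plaur, which encodes a receptor of migrating cells. Among those that fell were the aldehyde and alcohol dehydrogenases Aldh3a1 and Adh7, the quinone reductase Nqo1 and H2-Aa, which encodes a class II antigen presentation chain. No grouping of these genes by function was tested beyond the fixed lists. Cyp26b1 rose from 1.63 ± 0.76 to 16.3 ± 6.45 CPM (log2 3.32, SE 0.42, adjusted p = 0.0059), as did Aldh1a3, which makes retinoic acid (3.33 ± 1.32 to 14.2 ± 6.22 CPM, log2 2.09, adjusted p = 0.0244). Itga3 rose from 187 ± 18.4 to 508 ± 155 CPM (1.44, 0.0139), Hbegf from 10.8 ± 2.93 to 38.8 ± 16.4 CPM (1.84, 0.0249), and Plaur by 1.43 (0.0249). The squamous keratin Krt13 rose 4.8-fold (2.26, adjusted p = 0.0415), and Nccrp1, a gene of stratified epithelia, rose 14.3-fold (0.53 ± 0.35 to 7.60 ± 3.31 CPM). Slc16a3, a lactate exporter, rose by 1.96 (adjusted p = 0.0137). Aldh3a1 fell from 404 ± 60.8 to 118 ± 74.7 CPM (-1.78, adjusted p = 0.0244), and Adh7 (-1.44, 0.0457), Nqo1 (-1.01, 0.0442) and Ugdh (-0.85, 0.0244) fell too. H2-Aa fell from 35.9 ± 6.17 to 13.3 ± 1.92 CPM (-1.43, adjusted p = 0.0194), with reads of this polymorphic family uncertain. These calls rested on single libraries. Without normal diet replicate 1, edgeR called 0 genes, and the adjusted p was 0.0554 for Cyp26b1 and 0.105 to 0.223 for the other genes named here. Vitamin A replicate 3 had the highest mitochondrial share of the 18 libraries (3.822% of counts), the highest mean of adipocyte genes (log2 CPM 5.876) and the lowest correlation with its own group among the 3 (0.9488). Without it, 4 genes passed, and of those named here only Cyp26b1 and Aldh3a1 did (0.0554 to 0.177 for the others). Without normal diet replicate 3, 20 genes passed, and Krt13, Aldh1a3, Hbegf, Plaur, Ugdh, Nqo1, Adh7 and Aldh3a1 did not (0.0576 to 0.109). Krt13, Hbegf, Plaur and Adh7 were also lost without normal diet replicate 2 (0.0568 to 0.12). Without vitamin A replicate 2 the genes Krt13, Hbegf, Plaur, H2-Aa, Adh7 and Aldh3a1 were lost (0.0614 to 0.0932), and without vitamin A replicate 1 the count was 305.

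In the lists of that comparison, the retinoic acid targets again lay higher (median 0.28, 1 risen over all genes and 2 adjusted over the list alone, adjusted p = 0.00141, or 0.031 with an estimated correlation), though without Cyp26b1 they had an adjusted p of 0.0244 (0.127 with an estimated correlation). Retinoid handling genes split, with 2 risen and 1 fallen over all genes and 2 and 4 adjusted over the list alone (adjusted p = 0.952, or 0.371 without Cyp26b1); their median was 0.09 and their mean 0.19 while the test pointed down. Lrat (1.35, adjusted p = 0.366), Dhrs3 (-0.02, 0.978), Rarb (0.35) and Crabp2 (0.47) did not pass. Matrix and wound genes had 3 risen members over all genes and, adjusted over the list alone, 14 risen and 1 fallen (median 0.73, adjusted p = 4.14e-12, or 0.0545 with an estimated correlation). Of the oxidative stress genes 4 fell over all genes and, adjusted over the list alone, 9 fell and 1 rose (median -0.22, adjusted p = 5.83e-07, or 0.177 with an estimated correlation). All 35 cell cycle genes lay higher, with 0 past the threshold over all genes and 19 adjusted over the list alone (median 1.04, adjusted p = 6.04e-20, or 0.156 with an estimated correlation), such as Plk1 (2.09, adjusted p = 0.0781) and Mki67 (1.5, 0.174). Inflammatory genes had a median of 1.43 with 0 risen over all genes and 9 adjusted over the list alone (adjusted p = 1.83e-07, or 0.125 with an estimated correlation), such as Cxcl1 (1.86, adjusted p = 0.0964) and Il6 (3.20, 0.137). Immediate early genes had 2 risen members, Dusp1 (1.68) and Klf6 (0.76), and 7 adjusted over the list alone (median 0.76, adjusted p = 1.59e-09, or 0.177 with an estimated correlation). Both were lost without every single library but vitamin A replicate 1 (0.0631 to 0.249). Basal genes (median 0.41, 1 risen, 3 adjusted over the list alone, adjusted p = 8.47e-05, or 0.349 with an estimated correlation) lay higher and umbrella cell genes lower (-0.17, 0 changed, 6 fallen and 1 risen adjusted over the list alone, adjusted p = 0.00681, or 0.588 with an estimated correlation). Among these were Upk2 (-0.75, adjusted p = 0.0888), Upk3a (-0.94, 0.122), Krt14 (1.54, 0.351) and Krt5 (0.34, 0.542), none past the threshold. Without vitamin A replicate 1 Upk2 and Upk3a passed (0.0326 and 0.0206). Krt20 was at -0.44, Upk1b at -0.52, Upk1a at -0.64 and Cdkn1a at 0.38, also not past it. Lymphocyte markers (-1.50, adjusted p = 5.17e-05, or 0.261 with an estimated correlation), mast cell and eosinophil markers (-0.69, 0.00181; 0.283), adipocyte genes (2.11, 4.24e-06; 0.435), squamous genes (0.35, 0.0384; 0.456), neutrophil markers (0.94, 0.041; 0.314), mesothelium (-0.52, 0.00686; 0.367) and p53 targets (0.15, 0.0175; 0.239) likewise passed only with the preset correlation, given first. There were 90 genes past the threshold, 46 up and 44 down, 59 of them changed over 2-fold, and 2145 had an unadjusted p under 0.05. DESeq2 called 499 genes on all libraries, and a fit of only the 6 libraries of this comparison called 2. The count of 90 was 0 without normal diet replicate 1, 20 without normal diet replicate 3, 305 without vitamin A replicate 1 and 4 without vitamin A replicate 3.

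The authors' own tables of the diet comparisons list 231 named and unnamed features past an adjusted p of 0.05 in saline mice, 377 at 1 day and 5 at 3 days after cyclophosphamide. Of these, 224, 356 and 4 were among the genes tested here, and every one had the same direction in the edgeR fit. Both use the same libraries, so the shared direction is no independent support. In edgeR, 2, 86 and 1 of them passed the threshold and 152, 346 and 4 had an unadjusted p under 0.05. The authors' values for Cyp26b1 are log2 3.27 (adjusted p = 1.05e-05), 3.33 (9.33e-14) and 2.91 (3.76e-18) over the 3 conditions, and for Elf5 1.87 (9.24e-27), 0.98 (0.00661) and 1.45 (0.0115). Elf5 at 1 day after cyclophosphamide was chosen after its values were seen. Dhrs3 at 0.51 in saline mice (adjusted p = 7.66e-06) passes in their table, and Lrat does not in any of the 3 (adjusted p = 0.246, 0.409 and 0.0836).

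**Figure D2:**
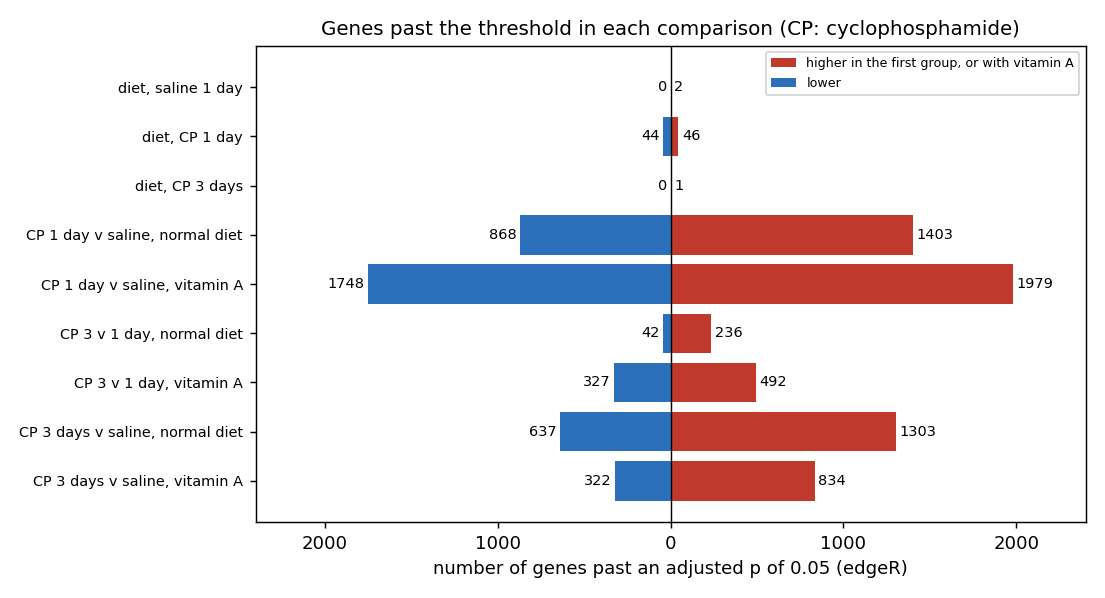
Number of genes past an adjusted p of 0.05 in edgeR for each comparison, with bars to the right for genes higher in the group named first or on the vitamin A diet and bars to the left for lower ones. Cyclophosphamide at 1 day gave 2271 genes on the normal diet and 3727 on the vitamin A diet, against 90 for the diet at that day. With only the groups compared in the fit, cyclophosphamide at 1 day gave more genes on the normal than on the vitamin A diet.

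At 1 day after cyclophosphamide on the normal diet, transcripts of cell cycle genes and p53 targets were higher than in saline mice. Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, rose from 52.0 ± 3.16 to 208 ± 25.1 CPM (log2 2.00, SE 0.13, adjusted p = 8.96e-08), and the division marker Mki67 from 2.5 ± 1.08 to 49.5 ± 19.6 CPM (4.33, 20.1-fold, adjusted p = 7.74e-05). All 35 cell cycle genes rose, over all genes and adjusted over the list alone (median 3.21, adjusted p = 8.83e-67, or 0.0187 with an estimated correlation), among them the replication helicase gene Mcm6 (4.07). Of 33 p53 targets 15 rose and 1 fell over all genes (16 and 1 adjusted over the list alone; adjusted p = 3.52e-12, or 0.00564 with an estimated correlation), including the death receptor gene Tnfrsf10b (1.82). Antioxidant genes followed, 18 of 25 risen and 1 fallen over all genes (20 and 1 adjusted over the list alone), led by Gpx2 (3.33, 10.1-fold) and Hmox1 (2.46); their adjusted p was 2.23e-16 (0.031 with an estimated correlation). The antimicrobial lectin Reg3g rose 91.9-fold, from 0.66 ± 0.46 to 57.3 ± 15.0 CPM. In the lining, the basal keratins Krt14 (1.87 ± 0.93 to 37.7 ± 12.8 CPM, 4.30, adjusted p = 0.00165), Krt5 (0.98, 0.00234) and Krt15 (1.86, 1.27e-05) rose, as part of 8 of 19 basal genes (11 risen and 1 fallen adjusted over the list alone; adjusted p = 6.64e-07, or 0.236 with an estimated correlation). Squamous genes had 8 risen members and 11 adjusted over the list alone (adjusted p = 7.12e-08, or 0.0679 with an estimated correlation), such as Krt4 (4.33) and Krt6a, whose ratio of 79.1 (95% counting interval 26.7 to 386) rests on few saline counts. The list of umbrella cell and urothelial differentiation genes moved both ways, 2 risen and 4 fallen over all genes, 4 and 6 adjusted over the list alone (adjusted p = 0.247). Upk2 fell from 1177 ± 35 to 648 ± 83.9 CPM (-0.86, adjusted p = 0.00542) and Krt20 fell too (-0.81, 0.00758), while Upk1a (-0.59, 0.0711), Upk3a (-0.54, 0.191) and Upk1b (-0.22, 0.503) did not pass. Transcripts of fibroblast genes fell, 16 of 21 over all genes and 18 adjusted over the list alone (median -1.33, adjusted p = 3.48e-22, or 0.107 with an estimated correlation), such as Col14a1 (278 ± 14.5 to 15.7 ± 4.16 CPM, 17.7-fold lower) and Scara5 (-4.09).

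Among immune and wound genes on the normal diet, 8 of 28 inflammatory genes rose and 1 fell (10 and 2 adjusted over the list alone), among them the alarmin Il33 (3.75) and the adhesion gene Icam1 (1.22), with an adjusted p of 1.32e-06 (0.147 with an estimated correlation). Il6 did not pass, at a ratio of 15.9 (2.44 to 669, adjusted p = 0.0909), but did without cyclophosphamide replicate 1 (0.0395). Of the matrix and wound genes 8 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000207, or 0.266 with an estimated correlation), such as the protease inhibitor Timp1 (3.36). Interferon genes had 9 risen members such as Zbp1 (2.74) (adjusted p = 3.43e-05, or 0.435 with an estimated correlation), and macrophage markers 5, such as Msr1 (2.46) (adjusted p = 0.000101, or 0.32 with an estimated correlation). The 1 lymphocyte marker that fell was the natural killer receptor Ncr1 (-4.07; list adjusted p = 0.0302, or 0.579 with an estimated correlation). Smooth muscle had 4 fallen members such as Synpo2 (-1.06, with 0.0612 and 0.054 without cyclophosphamide replicates 1 and 2) (adjusted p = 1.52e-05, or 0.514 with an estimated correlation). In all, 2271 genes passed, 1403 up and 868 down. That count was 1411 and 1262 without cyclophosphamide replicates 2 and 3, and 1335, 1402 and 1239 without saline replicates 1, 2 and 3. Krt20 had an adjusted p of 0.0505 without cyclophosphamide replicate 3, and Krt6a one of 0.0572 without saline replicate 3.

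On the vitamin A diet transcripts of cell cycle genes and p53 targets were higher too on that day. The list of umbrella cell and urothelial differentiation genes moved both ways, while its members Upk1a, Upk1b, Upk2, Upk3a and Krt20 fell. Mki67 rose from 4.98 ± 3.60 to 140 ± 47.5 CPM (log2 4.82, 28.2-fold, adjusted p = 9.81e-06) and Cdkn1a from 71.8 ± 3.11 to 270 ± 23.2 CPM (1.91, 1.79e-07). All 35 cell cycle genes rose, also adjusted over the list alone (median 4.12, adjusted p = 1.79e-70, or 0.0133 with an estimated correlation), and 15 p53 targets rose and 1 fell (16 and 2 adjusted over the list alone; adjusted p = 2.41e-12, or 0.00564 with an estimated correlation). Krt5 rose from 605 ± 37.5 to 2514 ± 637 CPM (2.05, adjusted p = 1.52e-06) and Krt14 from 3.16 ± 1.48 to 110 ± 31.9 CPM (5.13, 0.000186), among 12 of 19 basal genes (13 adjusted over the list alone; adjusted p = 2.09e-11, or 0.131 with an estimated correlation). Squamous genes had 14 risen members, also 14 adjusted over the list alone (adjusted p = 1.32e-06, or 0.107 with an estimated correlation), with Krt13 up 56.2-fold. The umbrella cell and urothelial differentiation list had 9 fallen and 5 risen members, 12 and 5 adjusted over the list alone (median -0.41, adjusted p = 0.029, or 0.664 with an estimated correlation). Upk2 fell from 1027 ± 42.2 to 385 ± 94.6 CPM (-1.42, adjusted p = 3.57e-05). So did Upk3a (-1.49, 0.000491), Upk1a (-1.25, 0.000283), Krt20 (-0.89, 0.0022) and Upk1b (-0.71, 0.0111, or 0.0622 without cyclophosphamide replicate 3). The growth factor genes Areg (6.73) and Hbegf (2.56) rose among 6 risen and 8 fallen members of their list, also 6 and 8 adjusted over the list alone (adjusted p = 0.276), and the hormone gene Fgf23 rose 127-fold. Inflammatory genes had 18 risen and 3 fallen members, 19 and 3 adjusted over the list alone (adjusted p = 1.51e-09, or 0.0705 with an estimated correlation), such as Il33 (4.77), Cxcl1 (4.76) and Il6, at a ratio of 158 (27.9 to 6309). Immediate early genes had 14 risen members and 17 adjusted over the list alone (adjusted p = 1.76e-11, or 0.142 with an estimated correlation), and matrix genes 16 risen and 2 fallen, 17 and 3 adjusted over the list alone (adjusted p = 6e-09, or 0.116 with an estimated correlation). Fibroblast genes fell, 15 over all genes and 18 adjusted over the list alone (median -1.34, adjusted p = 8.93e-18, or 0.142 with an estimated correlation), such as Col14a1 (266 ± 18.3 to 14.2 ± 8.40 CPM, -4.22). Lymphocyte markers had 9 fallen members and 10 adjusted over the list alone (adjusted p = 1.03e-05, or 0.243 with an estimated correlation), such as Ncr1, lower by at least 46.6-fold. In the retinoid pathway Cyp26b1 fell by 1.47 (adjusted p = 0.00879, or 0.0561 without saline replicate 2) and Lrat fell too (-2.48, 0.00316) while Aldh1a3 rose by 2.57 (0.000156), within a list that did not pass (4 risen and 7 fallen, adjusted p = 0.545). The falls of Cyp26b1 and Lrat were not shown to be particular to this diet. Their interaction of diet with cyclophosphamide was 0.07 (edgeR adjusted p = 0.993) and -0.16 (0.987), so their estimated falls were of similar size on the normal diet. Antioxidant genes had 11 risen and 4 fallen members, 13 and 5 adjusted over the list alone (adjusted p = 0.000207, or 0.318 with an estimated correlation). In all 3727 genes passed, 1979 up and 1748 down, and 2474 did without saline replicate 2.

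The responses to cyclophosphamide on both diets, which share no library, agreed in direction. Of 1590 genes past the threshold on both diets 1587 had the same sign, 1008 up where 144 are expected by chance and 579 down where 79 are. Across all 19323 genes, which are not independent replicates, the changes had a Pearson r of 0.601 and a Spearman rho of 0.548. The interaction of diet and cyclophosphamide, which tests whether the responses differ, gave 0 genes in edgeR at an adjusted p under 0.05 (smallest 0.09299), with 1505 at an unadjusted p under 0.05 and 120 called by DESeq2. The smallest adjusted p, 0.093, was shared by Gm39876 (3.24), the kinase receptor gene Epha2 (2.05), the glucose transporter gene Slc2a1 (1.26), H2-Aa (-1.95) and H2-Eb1 (-2.41), and Krt5 was at 1.08 (0.196), Aldh1a3 at 2.24 (0.196) and Cyp26b1 at 0.07 (0.993). Krt14 (0.83), Mki67 (0.49), Cdkn1a (-0.09), Krt20 (-0.08), Upk1b (-0.5), Upk2 (-0.56), Upk1a (-0.67) and Upk3a (-0.95) did not pass either, nor did Il6 (adjusted p = 0.824), for which no fold is given since each saline group had 1 count. Leaving out vitamin A replicate 1 or 2 of the cyclophosphamide groups gave 39 or 3 genes, saline normal diet replicate 3 gave 9 and saline vitamin A replicate 2 gave 2.

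**Figure D3:**
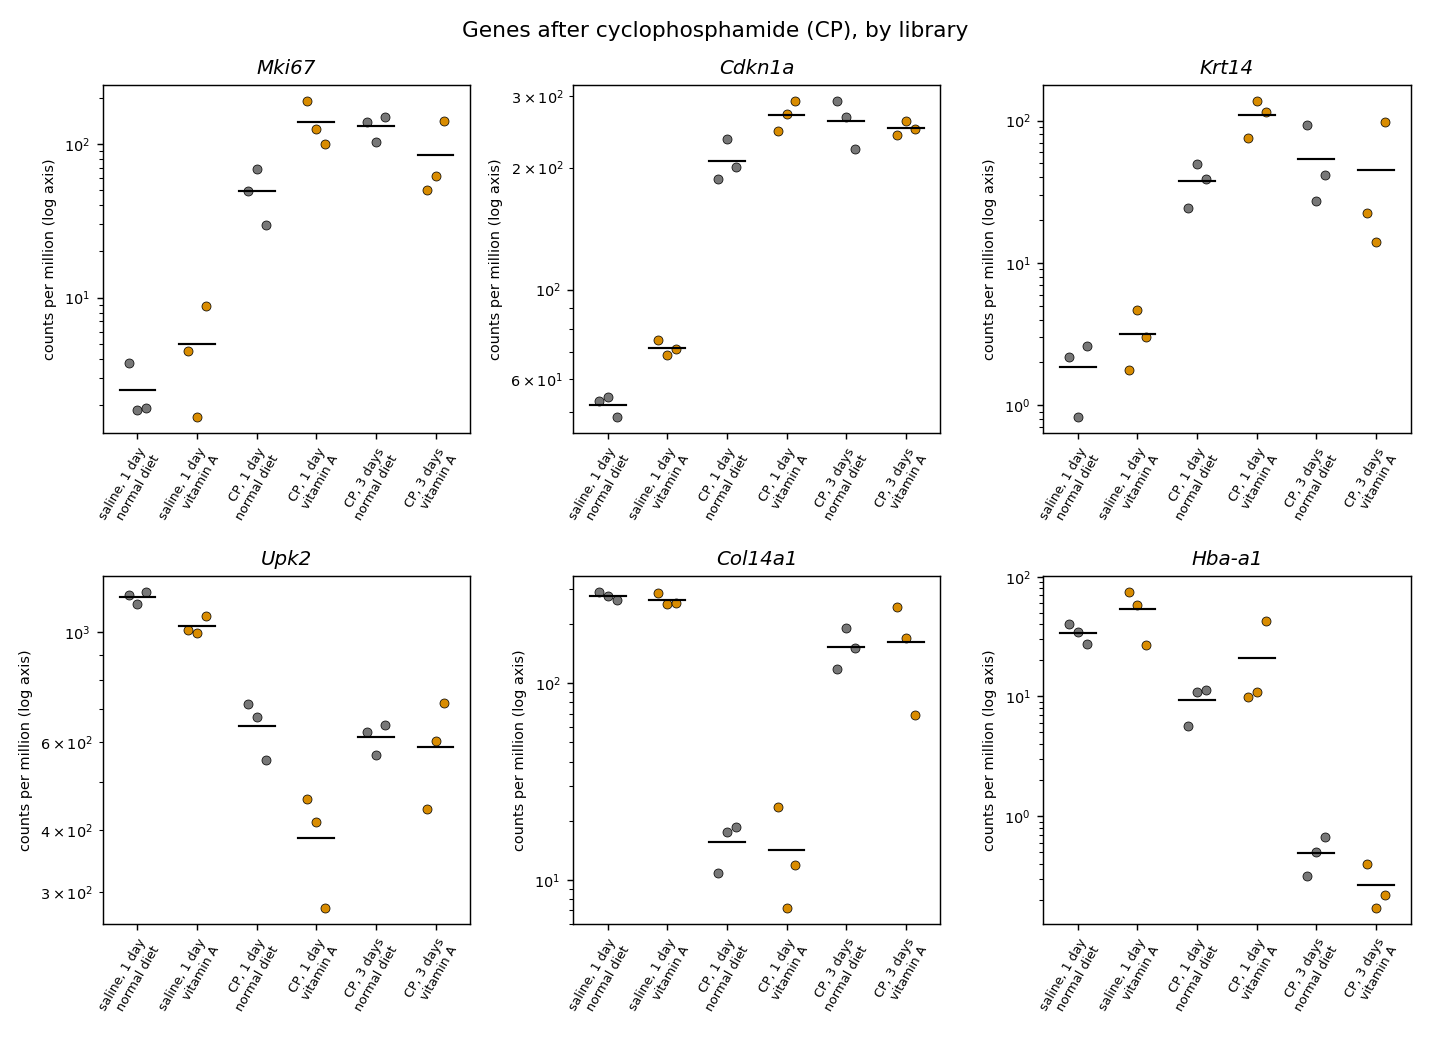
Expression of Mki67, Cdkn1a, Krt14, Upk2, Col14a1 and Hba-a1 in CPM on a log axis, with points for the 3 libraries of each group and bars for group means. Col14a1 fell 17.7-fold at 1 day on the normal diet and rose 9.78-fold from there to 3 days, while Hba-a1 fell 69.1-fold from saline to 3 days.

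From 1 to 3 days on the normal diet transcripts of connective tissue genes rose and those of red cell genes fell. Fibroblast genes rose, 12 of 21 over all genes and 19 adjusted over the list alone (median 1.46, adjusted p = 1.46e-37, or 0.031 with an estimated correlation). Col14a1 rose from 15.7 ± 4.16 to 154 ± 36.7 CPM (log2 3.29, adjusted p = 0.000315), the collagen gene Col1a1 from 423 ± 101 to 2669 ± 824 CPM (2.66, 0.000627) and Lox, whose enzyme crosslinks collagen, from 8.38 ± 1.00 to 55.4 ± 8.92 CPM (2.72, 8.88e-06). Haemoglobin genes fell, Hbb-bs (-7.87, adjusted p = 4.02e-05) and Hba-a1 (-4.24, 0.000673), while Hba-a2 was lower by at least 75.6-fold; 4 of 7 red blood cell genes fell (adjusted p = 1.52e-15, or 0.00564 with an estimated correlation). Antioxidant genes went back down, 3 fallen and 1 risen over all genes and 17 and 1 adjusted over the list alone (median -0.52, adjusted p = 2.98e-18, or 0.0246 with an estimated correlation). Cell cycle genes rose further in 2 members, Tpx2 (1.47) and Cenpf (1.82), and in 16 with 1 fallen adjusted over the list alone (median 0.89, adjusted p = 1.52e-06, or 0.506 with an estimated correlation), and Mki67 was at 1.40 (adjusted p = 0.179). Growth factor genes had 4 risen members such as Bmp4 (1.46) (adjusted p = 0.000203, or 0.0705 with an estimated correlation), matrix genes 4 such as Loxl2 (1.98) (1.3e-06, or 0.151 with an estimated correlation) and endothelium 2, Tie1 (0.99) and Tek (0.92) (3.19e-10, or 0.139 with an estimated correlation). Lining markers did not pass, with Krt5 at -0.29 (1990 ± 130 to 1625 ± 159 CPM, groups that do not overlap, as chance gives in 10% of genes), Krt14 at 0.51, Krt20 at 0.13, Upk2 at -0.07, Upk1a at -0.16, Upk1b at 0.07 and Upk3a at -0.03, with Cdkn1a at 0.32 and Il6 at 2.44, none past the threshold. In all 278 genes passed, 236 up and 42 down, with 2184 at an unadjusted p under 0.05. The count was 70 and 109 without 1-day replicates 1 and 3 and 113 and 130 without 3-day replicates 2 and 3. Tpx2, Cenpf, Tie1 and Tek were lost without 1-day replicate 1 (0.0893, 0.123, 0.121 and 0.153), and some of them without 1-day replicate 3 or 3-day replicates 1, 2 or 3 (0.052 to 0.107).

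Over the same days on the vitamin A diet fibroblast genes also rose, 14 over all genes and 17 adjusted over the list alone (median 1.33, adjusted p = 4.8e-26, or 0.0705 with an estimated correlation), with Col14a1 going from 14.2 ± 8.40 to 161 ± 88.5 CPM (log2 3.50, adjusted p = 0.000185). The neutrophil attractant Cxcl1 (-3.69, adjusted p = 0.000786), Il33 (-1.70, 0.0257) and the growth factor gene Hbegf (-1.63, 0.0126) fell. Immediate early genes had 7 fallen members and 11 adjusted over the list alone (adjusted p = 3.19e-10, or 0.155 with an estimated correlation) and inflammatory genes 4 fallen and 1 risen (adjusted p = 0.000959, or 0.312 with an estimated correlation). Krt5 fell by 1.0 (adjusted p = 0.00578), with 4 basal genes fallen over all genes and 7 adjusted over the list alone (adjusted p = 2.48e-05, or 0.311 with an estimated correlation), and 5 squamous genes fell (0.000528, or 0.218 with an estimated correlation). Cell cycle genes had 5 fallen members such as Cdc6 (-1.31) and 12 adjusted over the list alone (median -0.61, adjusted p = 8.55e-09, or 0.387 with an estimated correlation), and Mki67 was at -0.72 (0.415). Upk3a, an umbrella cell gene, rose by 1.11 (adjusted p = 0.0214), but not without 1-day replicate 2 (0.0674) or 3 (0.0957) or 3-day replicate 2 (0.0629). Upk2 (0.61), Upk1a (0.52), Upk1b (0.48), Krt20 (0.05), Krt14 (-1.29), Cdkn1a (-0.11) and Il6 (-1.12) did not pass. Macrophage markers rose in 5 members such as Lyz2 (1.94) (adjusted p = 0.00823, or 0.54 with an estimated correlation). Haemoglobin genes fell, Hbb-bs (-9.17) and Hba-a1 (-6.31), with 4 of 7 red blood cell genes fallen (adjusted p = 3.78e-13, or 0.00868 with an estimated correlation). In all 819 genes passed, 492 up and 327 down. The count was 1293, 366 and 316 without 1-day replicates 1, 2 and 3 and 1335 without 3-day replicate 3. A fit of only the groups compared gave 17 genes, sample quality weights 129 and leaving out the 2 libraries least like their group 237. One of these, 3-day replicate 2, had the lowest sample weight (0.152) and 13.11% of its counts on genes shorter than 1 kb. Il33 was lost without 1-day replicate 2 (0.0971) or 3 (0.103) or 3-day replicate 1 (0.104) or 2 (0.114), and Hbegf without 1-day replicate 3 (0.0752). The interaction of diet and time gave 0 genes in edgeR (smallest adjusted p = 0.1725), with 1732 at an unadjusted p under 0.05 and 87 in DESeq2, and Cyp26b1 at -0.42 (0.887). Mki67 was at -2.12 (0.328), Krt14 at -1.8 (0.571), Krt5 at -0.71 (0.434), Upk3a at 1.14 (0.347), Upk2 at 0.68 (0.448), Upk1a at 0.68 (0.504), Upk1b at 0.41, Krt20 at -0.08, Cdkn1a at -0.43 and Il6 at -3.56 (0.375). It was 1 without 1-day normal diet replicate 2, 1-day vitamin A replicate 2 or 3-day normal diet replicate 2, and 25 without 1-day vitamin A replicate 1.

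**Figure D4:**
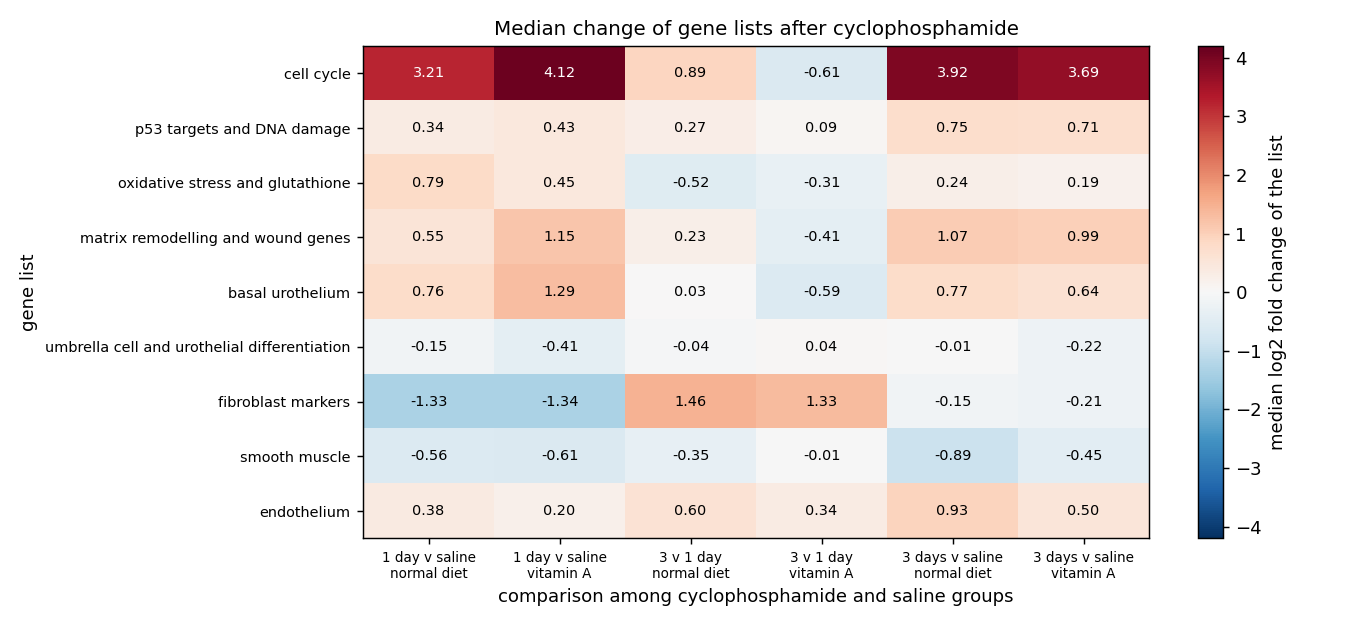
Median log2 change of 9 gene lists in the 6 comparisons among cyclophosphamide and saline groups, by colour and printed value. Cell cycle genes were higher than in saline in all 4 comparisons with it, while fibroblast genes fell at 1 day and rose from 1 to 3 days.

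At 3 days against saline on the normal diet, transcripts of cell cycle genes and p53 targets were high and red cell genes fell close to 0. Mki67 was at 131 ± 24.5 CPM against 2.5 ± 1.08 (log2 5.73, 53.1-fold, adjusted p = 6.06e-06) and Cdkn1a at 260 ± 35.7 against 52.0 ± 3.16 (2.32, 8.11e-09). All 35 cell cycle genes rose, also adjusted over the list alone (median 3.92, adjusted p = 4.8e-87, or 0.00862 with an estimated correlation), and so did 19 of 33 p53 targets, 25 risen and 1 fallen adjusted over the list alone (adjusted p = 4.96e-24, or 0.000579 with an estimated correlation). Hba-a1 fell from 34.1 ± 6.57 to 0.49 ± 0.18 CPM (-6.11, adjusted p = 2.89e-06) and Hba-a2 was lower by at least 175-fold, with 5 of 7 red blood cell genes fallen (4.14e-12, or 0.0133 with an estimated correlation). Matrix genes had 13 risen members and 16 adjusted over the list alone (adjusted p = 2.42e-13, or 0.031 with an estimated correlation), such as Loxl2 (2.01), and endothelium 12 and 13 adjusted over the list alone (adjusted p = 5.23e-12, or 0.107 with an estimated correlation), such as Eng (1.23). Macrophage markers rose in 13 members, such as Mrc1 (1.43), and 15 adjusted over the list alone (adjusted p = 9.3e-11, or 0.116 with an estimated correlation), and interferon genes in 12 such as Irf7 (1.67) (adjusted p = 2.51e-09, or 0.239 with an estimated correlation). Smooth muscle genes fell in 10 members such as Synm (-1.32), and 20 of 21 adjusted over the list alone (adjusted p = 1.14e-11, or 0.259 with an estimated correlation). Krt14 rose by 4.81 (adjusted p = 0.000757) and Upk2 fell by 0.93 (0.00318). Krt5 (0.68, adjusted p = 0.0266), Krt20 (-0.68, 0.0241) and Upk1a (-0.74, 0.0261) passed less firmly. Krt20 and Upk1a were lost without any 1 of the 6 libraries and Krt5 without any but 3-day replicate 2, with an adjusted p up to 0.116. Upk1b (-0.15) and Upk3a (-0.57) did not pass. Il6 rose at a ratio of 86.7 (15.3 to 3454). Fibroblast genes had 2 risen and 3 fallen members, 5 and 3 adjusted over the list alone (adjusted p = 0.363). In all 1940 genes passed, 1303 up and 637 down. The count was 961 and 1267 without 3-day replicates 1 and 3 and 1193, 1102 and 1105 without saline replicates 1, 2 and 3.

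On the vitamin A diet Mki67 was at 85.0 ± 49.8 CPM at 3 days (log2 4.10 over saline, 17.2-fold, adjusted p = 8.64e-05), Cdkn1a at 250 ± 9.73 CPM (1.80, 4.52e-07), and all 35 cell cycle genes rose, also adjusted over the list alone (median 3.69, adjusted p = 3.59e-85, or 0.00862 with an estimated correlation). Of the p53 targets 17 rose, and 22 rose and 1 fell adjusted over the list alone (adjusted p = 1.63e-26, or 0.00045 with an estimated correlation). Matrix genes had 13 risen members and 14 adjusted over the list alone (adjusted p = 2.33e-14, or 0.0298 with an estimated correlation). Red blood cell genes fell in 5 of 7 members (adjusted p = 6.37e-17, or 0.00564 with an estimated correlation), with Hba-a1 from 53.4 ± 24.5 to 0.26 ± 0.12 CPM (-7.65, adjusted p = 2.62e-06) and Hba-a2 lower by at least 322-fold. In the lining Krt5 (1.05, adjusted p = 0.00171), Krt14 (3.84, 0.0037) and the squamous Krt13 (3.84, 0.000188) rose and Upk2 (-0.81, 0.0125) and Krt20 (-0.85, 0.00828) fell. Upk1a fell by 0.73 (0.0404, but 0.0891 to 0.122 without 3-day replicate 1 or any saline replicate), and Upk1b (-0.23) and Upk3a (-0.38) did not pass. Il6 rose at a ratio of 75.8 (13.2 to 3034). Cyp26b1 fell by 1.42 (adjusted p = 0.0267), a call lost without every single library but saline replicate 3 (0.0515 to 0.152). On the normal diet Cyp26b1 had 2.27 ± 0.41 CPM at 3 days against 4.68 ± 2.82 CPM in saline mice. In all 1156 genes passed, 834 up and 322 down, and 750, 671 and 764 did without saline replicates 1, 2 and 3. A fit of only the groups compared gave 499.

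Other lists gave these results against saline, in the order of 1 day on the normal and the vitamin A diet and then 3 days on the normal and the vitamin A diet. Tight junction genes had adjusted p-values of 0.942, 0.952, 0.943 and 0.912, although single claudins changed, with Cldn8 fallen in all 4 (-1.39, -2.17, -1.15 and -1.28). Neutrophil markers had 0.0912, 0.0234 (0.281 with an estimated correlation), 0.146 and 0.257, and mast cell and eosinophil markers 0.67, 0.00498 (0.323 with an estimated correlation), 0.589 and 0.00593 (0.384 with an estimated correlation). Nerve and Schwann cell genes had 0.523, 0.861, 0.252 and 0.0463 (0.552 with an estimated correlation), mesothelium 0.897, 0.281, 0.11 and 0.269, and skeletal muscle 0.101, 0.473, 0.258 and 0.391. Adipocyte genes, 0 of which passed in these 4 edgeR comparisons, had 0.544, 0.721, 0.779 and 0.0302 (0.735 with an estimated correlation), and genes of the female genital tract and other epithelia 0.869, 0.972, 0.804 and 0.804.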

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

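The tests of a stronger cyclophosphamide response, of reads moving between haemoglobin copies and of the spread of the cyclophosphamide groups were chosen after the result was seen, as was DESeq2 on only the 6 libraries of a diet contrast.

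Gene lists differed between the diets in their response to cyclophosphamide at 1 day, by the interaction tested with camera at the preset correlation. The adjusted p was 2.2e-11 for immediate early genes, 2.84e-08 for cell cycle genes (median log2 0.51, a larger rise on vitamin A), 4.57e-06 for lymphocyte markers, 1.75e-05 for oxidative stress genes (-0.29), 3.46e-05 for matrix and wound genes (0.51) and 0.000119 for basal genes (0.31). It was 0.000209 for mast cell and eosinophil markers, 0.00768 for inflammatory genes, 0.0173 for retinoid handling, 0.0206 for macrophage markers, 0.0339 for interferon genes and 0.0442 for mesothelium. None of these held with an estimated correlation, where the adjusted p ran from 0.142 to 0.711. In the count of single genes, 3 of 100 divisions of the libraries, the real one among them, gave at least 1505 genes at an unadjusted p under 0.05. The real count was 1505 and the highest other 1549. These divisions redrew the diet labels in saline and cyclophosphamide mice alike, so a diet effect of any kind can make the share small. They cannot decide whether the responses to cyclophosphamide differ between the diets.

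The change from 1 to 3 days differed between the diets in the same kind of test. The adjusted p was 3.09e-23 for cell cycle genes (median -1.43, 0 of 35 above 0), 1.07e-09 for immediate early genes, 8.78e-07 for matrix and wound genes (-0.52), 3.49e-06 for oxidative stress genes (0.35) and 2.52e-05 for basal genes (-0.67). It was 0.00202 for inflammatory genes, 0.00502 for lymphocyte markers, 0.00663 for mesothelium, 0.00739 for adipocyte genes, 0.00863 for smooth muscle, 0.0223 for p53 targets and 0.0299 for endothelium. None held with an estimated correlation (0.139 to 0.711). Of 100 divisions 18 gave as many genes at an unadjusted p under 0.05 (real 1732, highest other 3175), so chance is not excluded.

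Features without a gene name, which the comparisons of the report do not use, also responded to cyclophosphamide. Of 1946 tested, 31 rose over saline at 1 day on the normal diet and 76 on the vitamin A diet, and at 3 days 19 and 20 did. In the same comparisons 15, 59, 10 and 5 fell.

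The 90 genes that changed with the diet at 1 day after cyclophosphamide were weighed against 3 explanations. More fat tissue in the vitamin A bladders was weighed in saline mice. There adipocyte genes also lay higher with the diet (median 2.33, against 2.11 at 1 day after cyclophosphamide). The 90 genes moved there by 0.06 of their change (95% bootstrap interval over genes 0.00352 to 0.0922). That interval does not measure the spread between mice, and genes chosen for a large change tend to move less elsewhere. Most of the 90 calls were also lost without 1-day vitamin A replicate 3, which had the highest mean of adipocyte genes (log2 CPM 5.876). The small share argues against fat tissue only weakly and does not exclude it. A gene length or RNA integrity effect stays open, with a chance of 0.605 that a risen gene is longer than a fallen one (0.48 to 0.722). Of the 90 genes, 72.2% moved with the diet as they did from saline to 3 days on the normal diet. A stronger or longer cyclophosphamide response on vitamin A would give such a share. Its binomial interval (61.8 to 81.1) treats genes of the same libraries as independent, so it does not measure the spread between mice. Across all genes these changes had a Pearson r of 0.157. A direct effect of the vitamin and the cage of the mice stay untested. The 10 splits of the 6 libraries are too few for a share under 0.05, and 1 of them, the real one, gave 90 genes while the highest other gave 3.

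Haemoglobin transcripts near 0 at 3 days were weighed against less blood left in the tissue and against reads moving between near-identical copies. Summed over the copies they had 103.7 and 185 CPM in saline mice on the normal and the vitamin A diet and 0.5665 and 0.3107 CPM at 3 days. Less blood would lower platelet transcripts too, and their median log2 change was 1.04 (0.16 to 1.92), from 3 genes, of which Ppbp lay under 1 CPM and Gp1bb had 0.9645 CPM in saline mice on vitamin A, so the test argues against it only as far as so few genes at low levels can. Moved reads would leave other red cell genes in place, and the smaller fall of Alas2, a single-copy gene of haem synthesis, was -2.35. A loss of young red cells from the blood after cyclophosphamide may be the source, but blood counts were not used here, so it stays an untested hypothesis.

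The small number of diet genes in saline mice, 2 here against 231 in the authors' table, was weighed against the pooling of spread over all groups. The common dispersion of the cyclophosphamide groups averaged 2.83 times that of the saline groups, which is consistent with a shared fit that is too strict for saline mice. Most of this came from the vitamin A groups after cyclophosphamide, at 0.1097 at 1 day and 0.153 at 3 days, against 0.04415 and 0.05033 on the normal diet and 0.02909 and 0.03409 in saline mice on the normal and the vitamin A diet. For contrasts with those 2 groups the shared fit may be too lenient. With the groups alone the diet at 1 day gave 2 genes in place of 90, 3 days against 1 day on vitamin A 17 in place of 819, 3 days against saline on vitamin A 499 in place of 1156 and cyclophosphamide at 1 day on vitamin A 3405 in place of 3727. The diet at 3 days gave 1 in both, and the interaction with cyclophosphamide 19 in place of 0. For cyclophosphamide against saline and for 3 days against 1 day, the groups alone gave more genes on the normal diet than on vitamin A. At 1 day against saline and from 1 to 3 days this reversed the order of the shared fit. Fewer samples in a fit can lower a count too, and these values do not separate that from the spread. On the 6 saline libraries alone edgeR gave 35 genes and DESeq2 248. The 10 splits are too few for a share under 0.05. Under DESeq2 no other split gave as many as the real 248 genes, and the highest other gave 51. Under edgeR, in the shared fit, the real split gave 2 genes and the highest other 0. A difference between the diets in cage or fat content of the samples was not tested by these values.

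For the other contrasts 10 splits are likewise too few for a share under 0.05. At 3 days after cyclophosphamide 2 of the 10 splits gave at least the real 1 diet gene, with 2 in the highest other. For cyclophosphamide at 1 day the real split gave 2271 genes on the normal diet and 3727 on vitamin A. The highest others gave 10 and 0, so no other split was as large. For 3 days against saline the real splits gave 1940 and 1156, the highest others 0 and 0. For 3 days against 1 day the normal diet gave 278 and the highest other 0. On the vitamin A diet the real split gave 819 and another 645, which points to a structure of these samples beside the day.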

How the results depend on the processing

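Tests chosen after the data were seen were the unnamed features included, the fit without the 2 libraries least like their group, limma-voom with sample quality weights, DESeq2 on the 6 libraries of a diet contrast and the retinoid lists without Cyp26b1. There were 557 calls of a named gene in a contrast, where a gene can count in several contrasts. Of their 7868 values under an alternative, 6837 kept their direction and side, 1031 lost the threshold and 0 reversed (edgeR, DESeq2 and limma together). All alternatives reuse the same libraries, so the lack of reversals is no independent support. Counts of genes moved more, and the cause was not tested beyond the spread of the groups given above. Those values do not separate spread from the number of samples fitted. The order below is diet in saline mice, diet at 1 day and diet at 3 days, where the counts were 2, 90 and 1. DESeq2 gave 17, 499 and 11, DESeq2 on the 6 libraries 248, 401 and 6, and only the groups of the contrast 35, 2 and 1. No filter gave 7 in saline mice and 0 at 3 days, limma on FPKM 154 at 1 day and 2 at 3 days, and sample weights 244 in saline mice and 7 at 3 days. At 3 days the replicate number as a block gave 0 and leaving out the 2 libraries 0, although replicate numbers do not pair the samples. Leaving out 1 library gave 0 to 2, 0 to 305 and 0 to 1 genes. For cyclophosphamide at 1 day on the normal diet (2271) the fit without the 2 libraries gave 3614, the groups alone 4463 and sample weights 5458, and leaving out 1 library 1239 to 1571, or 2474 to 3926 on vitamin A (3727). For 3 days against 1 day on the normal diet (278) the values were 500 without the 2 libraries, 664 with DESeq2, 708 for the groups alone, 2220 with weights and 70 to 257 with 1 library left out. On vitamin A (819) they were 237, 1726, 17, 129 and 316 to 1335. For 3 days against saline the groups alone gave 3710 and weights 5689 on the normal diet (1940), with 961 to 1559 on leaving out 1 library. On vitamin A (1156) DESeq2 gave 1766, the groups alone 499, weights 2850 and leaving out 1 library 671 to 1664. The interaction with cyclophosphamide (0 in edgeR, 1505 at an unadjusted p under 0.05) had 25 without the filter, 10 without the 2 libraries, 120 with DESeq2, 19 for the groups alone, 183 with weights and 0 to 39 with 1 library left out. The interaction with time (0, 1732 unadjusted) had 9 without the filter, 87 with DESeq2 and 0 to 25 with 1 library left out. RLE scaling moved no count by over 1.5 times. Of 141 list calls 120 were lost with an estimated correlation and 4 with the block.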

Other observations

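The test of a diet effect averaged over the 3 conditions was chosen after the single comparisons were seen. It asks which genes differ with vitamin A on average over the conditions, and edgeR called 15 genes, 9 higher and 6 lower, with 1448 at an unadjusted p under 0.05. Cyp26b1 (log2 3.16, adjusted p = 1.41e-06), Elf5 (1.43, 8.71e-05), the lipid droplet gene Hilpda (1.13, 0.00247), Padi1 (1.16, 0.005), Pdk4 (0.64, 0.00592), Cd14 (0.76, 0.0121), Hk2 (0.65, 0.0142), Omp (0.92, 0.0156) and Cd24a (0.44, 0.0385) rose. Fstl4 (-1.81, 0.005), Ank (-0.55, 0.00592), Apcdd1 (-0.69, 0.00989), Gsdma (-1.10, 0.0156), Fcrls (-1.03, 0.0156) and Adamdec1 (-0.52, 0.0427) fell. In 100 divisions of the libraries within conditions 1, the real one, gave 15 genes, and the highest other gave 6. This is the smallest share that 100 divisions can give. The test was chosen after Cyp26b1 and Elf5 had been seen to rise in the same libraries, so the share does not exclude chance at its nominal level. The 15 genes were chosen by their average over the 3 conditions, which by itself favours a shared sign. All but Adamdec1 (0.06 in saline mice, -1.23 at 1 day and -0.39 at 3 days) had the same sign in the 3 conditions. Those genes may hold a diet response shared by the conditions, a hypothesis from the same libraries, with cage and diet not told apart by the design.

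Adipocyte genes varied widely between single bladders, with a mean log2 CPM per library from 0.7711 to 5.876. The share of counts on genes shorter than 1 kb was 13.11% in 1 library (vitamin A diet, 3 days after cyclophosphamide, replicate 2) against 9.907% in the next highest.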
